A study of Gallus gallus with 6 samples.

How the data were processed

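Small RNA was sequenced from leg muscle of Xinghua chicken, a breed of Gallus gallus, at 3 ages: embryonic day 11 (E11), embryonic day 16 (E16) and day 1 after hatching (P1). Each age had 2 samples, all from females per the labels. RNA was extracted with Trizol and libraries followed Illumina protocols, per the labels' protocols. The labels also describe the RNA as RNase R treated and depleted of ribosomal RNA, which is the wording of another kind of RNA library, and what this meant for the miRNA libraries is not given in the sources used here. Trim Galore, Bowtie, TopHat, Cufflinks and the chicken genome build galGal4 are named in the submitters' processing notes, without a role or a version for any of them. The program that assigned reads to miRNAs is not given in the sources used here.

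The deposited values were used as counts of reads per miRNA, although the file headers call the same column FPKM. Every value was a whole number, 1 was the most frequent value in each file, and column totals differed between samples, from 303556 to 2641042. A header that is right and values that had been rounded would make the count tests below unsuitable, and the header could not be reconciled with the values from the sources used here. Each of the 6 files held 1 sample and listed only miRNAs with a value of at least 1, so a miRNA missing from a file was given a count of 0.

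The files listed 846 distinct mature sequences. Of these, 534 carried a miRBase-style chicken name, given here without its species prefix, and 312 carried a provisional identifier that the files do not pair with a name. Provisional identifiers took between 32.1% and 42.9% of the counts of a library. They entered library sizes and tests and were left unnamed. In 9 pairs of entries the counts agreed within 10% in every library, or by no more than 3 counts. These pairs include let-7a-5p with let-7j-5p, and miR-10b-5p, miR-125b-5p, miR-146c-5p, miR-181a-5p and miR-31-5p each with a provisional entry. The same reads appear to have been listed under both names, so values of these miRNAs are uncertain to that extent, and library totals hold such reads more than once. No genome was used here, so no positions are given.

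Counts were analysed in R 4.3.3 with edgeR 4.0.16. Entries were kept by filterByExpr with its minimum count of 10 and minimum total of 15, which left 289 entries, 199 of them named. Libraries were scaled by TMM, and CPM below means TMM-normalized CPM, the usual scaling of counts to a common total. A quasi-likelihood model with 1 coefficient per age was fitted to all 6 samples, leaving 3 residual degrees of freedom, and each of the 3 pairs of ages was compared with a two-sided F-test. P-values were adjusted by Benjamini-Hochberg within a comparison, with a threshold of 0.05. "Rose" and "fell" are used only for miRNAs or lists past that threshold. The standard error (SE) of a log2 fold change was its size divided by the square root of its F statistic. The biological coefficient of variation was 0.467. The labels do not say that the samples of an age came from separate animals, so the p-values measure only the spread between these samples, which may be technical. Replicates were compared before averaging. Their counts differed by far more than sampling noise, with a chi-square per degree of freedom of 264 at E11, 171 at E16 and 489 at P1, so each was kept as a separate sample.

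Before the data were examined, 24 miRNA lists were fixed (families, clusters and markers of muscle and other cell types), along with the comparisons, the tests and the rule for naming miRNAs. Lists with at least 3 tested members were tested with camera in limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation, with adjustment over the 15 lists tested. The fry test, which asks whether the members of a list move one way on balance and does not compare them with other entries, was run beside it with the same adjustment. By the rule, the text names up to 8 miRNAs with the largest rise and 8 with the largest fall per comparison, among named entries past the threshold whose samples did not overlap between ages. Where none passed, it names the 5 with the smallest p. It also takes the 10 most abundant named miRNAs and up to 4 abundant members of each list. The restriction to named entries was made after the files were seen. Other miRNAs named below were chosen after their values were seen, including miR-193a, miR-455, miR-2188-5p, miR-19a-5p, miR-92-5p, miR-18b-3p, miR-17-3p, let-7c-3p, miR-301a-5p, miR-301b-5p and miR-3607-3p.

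The share of counts taken by the muscle list was compared between ages by an exact two-sided permutation test, whose smallest possible p with 2 samples against 2 is 0.333. Where an age held 1 to 3 counts of a miRNA, the ratio of summed counts scaled by effective library size was given with its exact binomial 95% interval, which covers counting error only. The same holds for all intervals below, since sequencing reads without molecular identifiers are not independent molecules. Alternatives were other scalings (RLE, upper quartile, library size only), DESeq2 1.42.0, limma-trend on log2(CPM + 1), other filters, fits of 4 samples, a replicate block and the removal of each library. Alternatives added after seeing the data were the use of named entries only, the merging of near-identical entries, thinning to the smallest library and removal of the epithelial list.

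The procedure was tested on simulated counts drawn from the real means and library sizes, with 200 entries changed. Among changed entries that passed the filter, 31.1% of 4-fold and 85.3% of 16-fold changes were recovered for E16 against E11, 69.0% and 100% for P1 against E16, and 42.9% and 90.7% for P1 against E11. False calls numbered 0, 5 and 1 in these comparisons. In 100 simulations without any change between ages, the 3 comparisons together gave a mean of 0.13 called entries and 0.06 called lists. In all these simulations each entry was drawn on its own, with a spread set by a trend over abundance. Members of a list were thus uncorrelated, so the 0.06 cannot show how often camera calls lists of correlated members. The recovery rates hold for that spread only.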

Results

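The leg muscle miRNA profiles covered E11, E16 and P1, with 2 female samples of each age. Total counts were 303556 and 589154 at E11, 1202481 and 948589 at E16, and 2641042 and 2201359 at P1, so the E11 libraries were the shallowest and rare miRNAs were measured least precisely there. Between 453 and 578 entries were listed per library, and the 10 most abundant took between 61.2% and 65.7% of a library's counts. Of the 846 entries, 317 were listed in all 6 libraries.

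The most abundant named miRNAs were of a mixed kind. miR-148a-3p had a mean of 61035 ± 10306 CPM at E11, 77810 ± 4474 at E16 and 79798 ± 4678 at P1 (SD, n = 2). miR-10b-5p, encoded within a HOX cluster, had 75768 ± 3471, 76901 ± 23464 and 63063 ± 2670 CPM at the same ages. miR-181a-5p had 52904 ± 30806, 52377 ± 2740 and 61355 ± 10455 CPM, and its 2 E11 libraries lay far apart. miR-133a-3p, the muscle-specific miRNA processed from the miR-1/miR-133 clusters, went from 3383 ± 229 CPM at E11 to 42437 ± 6922 at E16 and 103769 ± 50125 at P1. miR-22-3p had 27497 ± 4591, 57497 ± 977 and 84572 ± 1873 CPM. At P1 miR-133a-3p had the highest mean of the named miRNAs, but this rested on replicate 2 (139213 CPM): in replicate 1 it had 68326 CPM, below miR-22-3p (85897) and miR-148a-3p (76489). miR-10a-5p had 53088 ± 56912, 23029 ± 10011 and 31130 ± 816 CPM, with 12845 CPM in the first E11 library and 93330.2 CPM in the second. The other 4 of the 10 were miR-126-5p, miR-499-5p, let-7f-5p and miR-30c-5p. Among all entries, an unnamed one had the highest mean over the 6 libraries (83194 CPM). Another unnamed entry had 41209, 53162 and 109542 CPM at E11, E16 and P1, at P1 above the mean of miR-133a-3p.

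The list of muscle-enriched miRNAs (miR-1, miR-133, miR-206, miR-208, miR-486 and miR-499) took 1.16% ± 0.172 of all counts at E11, 7.64% ± 0.391 at E16 and 13.7% ± 2.35 at P1 (SD, n = 2). The 2 samples of each age did not overlap with those of another. The exact permutation test gave p = 0.333 for each pair of ages, the smallest p that this design allows, so it cannot pass a threshold of 0.05.

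**Figure D1:**
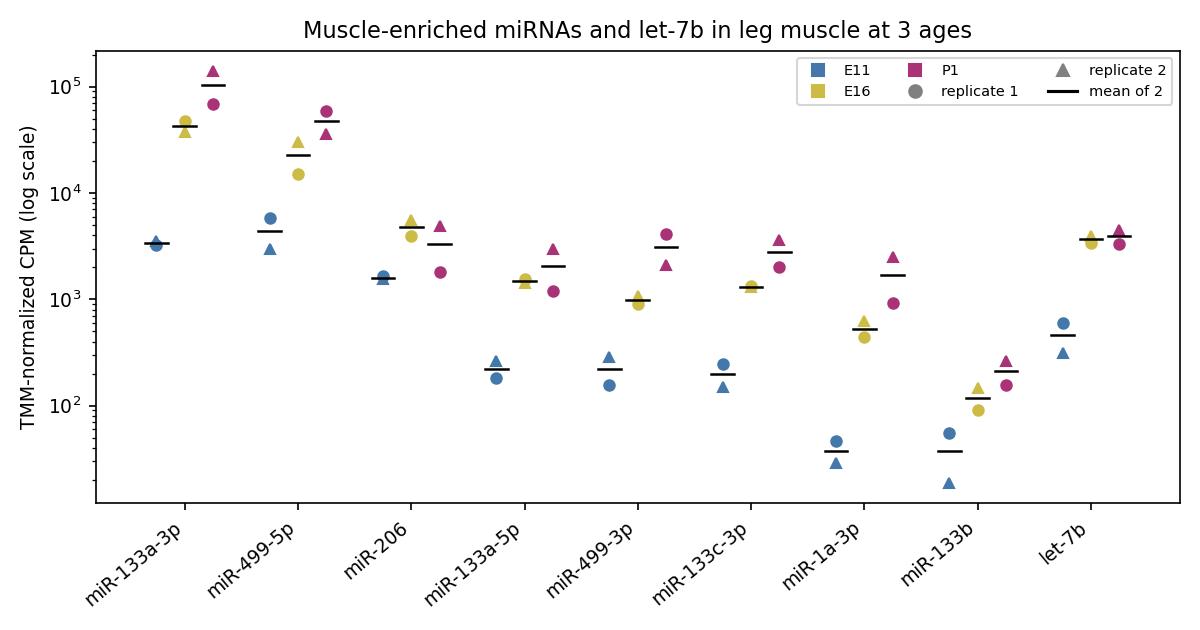
TMM-normalized CPM (log scale) of 8 muscle-enriched miRNAs and let-7b in each library, with colours for age, symbols for replicate and a bar for the mean of 2 samples. miR-133a-3p has a mean of 3383 CPM at E11 and 103769 at P1, while miR-206 has 1601, 4760 and 3336 CPM at the 3 ages.

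The comparison of E16 with E11 asked which miRNAs differed between 2 stages of embryonic muscle growth. Muscle miRNAs were higher at E16. miR-1a-3p, which with miR-133 marks differentiated striated muscle, rose 14.2-fold (log2 fold change 3.83, SE 0.66), and miR-133a-3p rose 12.5-fold (3.65, SE 0.43), with 2 samples per age. miR-1a-3p had only 16 and 20 counts in the E11 libraries (37.8 ± 12.7 CPM, SD, n = 2), against 530 ± 128 CPM at E16. miR-499-5p, processed from an intron of a slow myosin gene, rose 5.11-fold (2.35, SE 0.51), but lost its call in 16 of 21 alternatives, which include each of the 6 fits without 1 library, where its log2 fold change lay between 1.92 (adjusted p = 0.299, without E16 replicate 2) and 3.03 (adjusted p = 0.0698, without E11 replicate 1). let-7b, a member of the let-7 family that accumulates in differentiating tissues, rose 8.04-fold (3.01, SE 0.46). In the other direction, miR-205a and miR-205b, found in epithelia, were 74.8-fold and 41.4-fold lower at E16 (-6.23, SE 1.15, and -5.37, SE 0.63).

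Of the 10 tested members of the muscle list, 5 rose and none fell at E16, and 9 rose when adjusted over the list alone. Besides those above, these 5 included miR-133a-5p (2.74, SE 0.54) and miR-133c-3p (2.74, SE 0.48). miR-206, the muscle miRNA already present in embryonic myoblasts, had 1601 ± 73.0 CPM at E11 and 4760 ± 1148 at E16 (SD, n = 2) and did not pass (log2 fold change 1.57, edgeR Benjamini-Hochberg adjusted p = 0.116), nor did miR-499-3p (2.17, adjusted p = 0.0544). The list as a whole rose in camera (median log2 fold change 2.26, adjusted p = 4.86e-09), with adjusted p = 0.306 with an estimated correlation and 0.0513 in fry.

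Epithelial markers (miR-141, miR-200, miR-203, miR-205 and miR-429) fell as a list in camera (median -5.45, adjusted p = 4.32e-07), with adjusted p = 0.479 with an estimated correlation and 0.109 in fry. Among 7 tested members, 3 fell and none rose, and 6 fell when adjusted over the list alone. The third was miR-200a-5p, with 71 counts at E11 and 3 at E16, a ratio of 50.7 with a 95% interval of 16.7 to 252. miR-429-3p (log2 fold change -6.34) and miR-200b-3p (-5.08) had edgeR Benjamini-Hochberg adjusted p = 0.0656 and 0.106. miR-203a had -2.07 (adjusted p = 0.482). Without E16 replicate 1 these 3 had -8.19, -7.39 and -3.74, while miR-429-3p had -4.40 and miR-200b-3p -3.02 without E11 replicate 2, and miR-203a had -1.18 without E16 replicate 2. The median of the list was -6.61 without E16 replicate 1 and -4.43 without E11 replicate 2. The list took 1.18% and 1.21% of the counts of the E11 libraries and 0.0302% ± 0.0204 at E16 (SD, n = 2). Epithelial markers differed between the same ages as the muscle miRNAs, and without the epithelial list 13 entries passed at E16.

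miR-126-5p, an endothelial miRNA, rose 2.82-fold (log2 fold change 1.49, SE 0.31) but lost its call in each of the 6 fits without 1 library, 8 of 21 alternatives in all. The remaining named calls were the low-count miRNAs miR-3528, miR-1677-3p and miR-1625-5p, which fell. miR-3528 had 21 counts at E11 and 1 at E16, a ratio of 45.0 (95% interval 7.24 to 1861), and miR-1677-3p had 20 and 3, a ratio of 14.3 (4.24 to 75.1). Their calls were lost in 5 of 17 and 6 of 18 alternatives, among them each of the 5 fits without 1 library that tested them. miR-1625-5p fell by 3.54 on the log2 scale, but lost its call in 13 of 20 alternatives, each of the 6 fits without 1 library among them. miR-140-3p, a cartilage miRNA, had 914 and 146 CPM in the E11 libraries and 57.4 ± 12.3 CPM at E16 (SD, n = 2). With all 6 libraries it did not pass (-3.20, edgeR Benjamini-Hochberg adjusted p = 0.0836). It had -1.22 without E11 replicate 1 and -4.01 without E11 replicate 2. In the let-7 list let-7b alone passed among 14 tested members. Camera did not call that list (median 0.62, adjusted p = 0.0801), and its median was 1.22 without E11 replicate 1. Over all entries, no member passed in the other tested lists, which were miR-17-92, HOX-embedded miR-10 with miR-196, miR-199 with miR-214, miR-30, miR-15 with miR-16, miR-181, the miR-23, miR-24 and miR-27 clusters, miR-221 with miR-222, miR-130 with miR-301, erythroid, leukocyte and neural, and neither camera nor fry called these. Adjusted over the list alone, miR-222a (-1.41, adjusted p = 0.0194) and miR-221-3p (-1.03, adjusted p = 0.0429) fell, 2 of the 3 members of miR-221 with miR-222, whose fry adjusted p was 0.0513, and no member of the other lists passed. Of the 15 lists fry called 0, while 5 had an unadjusted fry p under 0.05, and its test for change in either direction called 6.

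In all, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 19 of 289 entries at E16 against E11, 7 higher and 12 lower, of which 6 of the lower ones were unnamed. Adjusted p was 0.00558 for miR-133a-3p and miR-205b, 0.0147 for let-7b, 0.0213 for miR-1a-3p and 0.0240 for miR-205a. It was 0.0360 for miR-126-5p and 0.0392 for miR-499-5p. In all 19 the samples of E11 and E16 did not overlap in CPM. Leaving out 1 library could therefore hardly reverse a direction, and a kept direction says little about stability. None of the 19 was called in every fit that left out 1 library, although all 19 kept their direction where still tested: the count was 0 without either E16 library, 11 without E11 replicate 1, 6 without E11 replicate 2 and 10 without either P1 library. For 8 of the 19 the fold moved by over 1.5 times in at least 1 of these fits, among them let-7b (3.68 without E11 replicate 1), miR-499-5p, miR-205a (-5.62 without E11 replicate 1), miR-1625-5p (-2.71 without E16 replicate 1 and -4.85 without E16 replicate 2), miR-1677-3p (-3.04 without E16 replicate 1) and miR-3528 (-7.55 without E16 replicate 1 and -4.24 without E16 replicate 2). miR-133a-3p had 3.52 (adjusted p = 0.0927) without E16 replicate 1 and 3.99 (adjusted p = 0.131) without E16 replicate 2.

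The comparison of P1 with E16 asked what differed across hatching. No single miRNA passed in edgeR, where 37 entries had an unadjusted p under 0.05 (25 higher and 12 lower at P1) and the smallest Benjamini-Hochberg adjusted p was 0.224. DESeq2 called 2, miR-146a-5p and an unnamed entry. The 5 smallest p-values belonged to miR-146a-5p, miR-146a-3p and miR-146b-5p, which are induced in inflammatory signalling, to miR-29b-3p and to miR-194. miR-146a-5p had 20.8 ± 4.54 CPM at E16 (SD, n = 2) and 106 and 82.0 CPM in the P1 libraries, a log2 fold change of 2.17 (SE 0.48). miR-146b-5p had 2.87 (SE 0.72), miR-146a-3p 2.03 (SE 0.51) and miR-194 -2.89 (SE 0.67). miR-29b-3p had 3 counts at E16 and 68 at P1, a ratio of 12.3 (95% interval 4.04 to 61.1, for counting error only). Without E16 replicate 1 and without E16 replicate 2 its fitted log2 fold change was 7.32 and 2.63, and without E16 replicate 1 that of miR-146b-5p was 3.56.

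At the level of lists, 5 rose in camera from E16 to P1, each with no member past the threshold over all entries. Fry called 0 of the 15 lists, while 4 had an unadjusted fry p under 0.05, and its test for change in either direction called 3. The muscle list had a median log2 fold change of 1.09 (adjusted p = 0.0112, adjusted p = 0.404 with an estimated correlation and 0.174 in fry), with miR-133a-3p at 1.29 (SE 0.40), miR-1a-3p at 1.69 (SE 0.59) and miR-206 at -0.51 (SE 0.50), which became 0.69, 0.81 and -1.40 without P1 replicate 2, and 0 of 10 members passed when adjusted over the list alone. The leukocyte list (miR-142, miR-146, miR-155 and miR-223) had a median of 0.94 (adjusted p = 0.0112, adjusted p = 0.404 with an estimated correlation and 0.174 in fry). When adjusted over the list alone 3 of 8 members passed, which were miR-146a-5p, miR-146a-3p and miR-146b-5p. miR-142-5p (1.23), miR-142-3p (0.24) and miR-223 (0.66) did not pass. The share of counts of the list went the other way, from 0.918% at E16 to 0.756% at P1. Its most abundant member, miR-146c-5p, had -0.06 (SE 0.42). The erythroid list (miR-144 and miR-451) had a median of 1.89 (adjusted p = 0.0275, adjusted p = 0.549 with an estimated correlation and 0.361 in fry), and 2 of 3 members passed when adjusted over the list alone. The miR-30 family had a median of 0.95 and the miR-23, miR-24 and miR-27 clusters 1.00, both with adjusted p = 0.0445, both with adjusted p = 0.404 with an estimated correlation, with 0.174 and 0.102 in fry, and neither with a member passing when adjusted over the list alone.

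The 5 calls depended on single libraries. miR-451, which is abundant in red blood cells, had 32080 CPM in P1 replicate 1 and 6939 CPM in replicate 2, and 3759 ± 1939 CPM at E16 (SD, n = 2). Without P1 replicate 1 the erythroid median was 0.81 (adjusted p = 0.514) and the leukocyte median -0.05 (adjusted p = 0.284) while camera's direction for the latter stayed upward. Both lists also lost their calls without E11 replicate 1 (1.85, adjusted p = 0.108, and 0.90, adjusted p = 0.0607) and without E16 replicate 2 (1.57, adjusted p = 0.166, and 0.58, adjusted p = 0.0789). The muscle list lost its call without P1 replicate 2 (0.63, adjusted p = 0.278) and without E16 replicate 1 (0.62, adjusted p = 0.150). The miR-30 list and the list of the miR-23, miR-24 and miR-27 clusters lost theirs without any 1 of the 4 E16 and P1 libraries, with adjusted p between 0.0606 and 0.213. The number of lists called was 3 without E11 replicate 1, 1 without E16 replicate 2, 2 without E16 replicate 1 or P1 replicate 2, and 2 without P1 replicate 1, where only the muscle list of the 5 was kept and the epithelial list was called lower instead (median -3.59, adjusted p = 0.000442). The other 10 tested lists, epithelial markers among them (median -0.79, adjusted p = 0.344), did not pass.

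**Figure D2:**
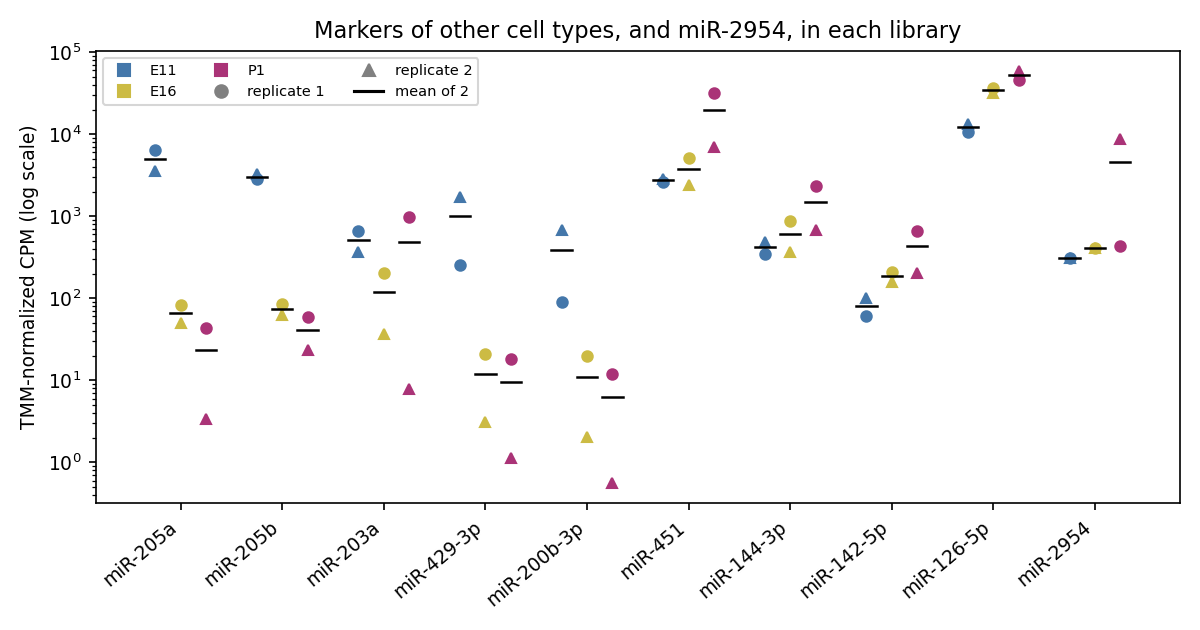
TMM-normalized CPM (log scale) of markers of other cell types and of miR-2954 in each library, with colours for age, symbols for replicate and a bar for the mean of 2 samples. miR-205a has a mean of 4980 CPM at E11 and 23.5 at P1, and miR-451 has 32080 and 6939 CPM in the 2 P1 libraries.

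The comparison of P1 with E11 spanned the whole series. Among the 15 tested lists, muscle miRNAs had the highest median change and epithelial miRNAs the lowest. miR-1a-3p rose 45.8-fold (log2 fold change 5.52, SE 0.71), miR-133a-3p 30.7-fold (4.94, SE 0.46), miR-133c-3p 14.2-fold (3.83, SE 0.50), miR-499-3p 14.0-fold (3.80, SE 0.55) and miR-499-5p 10.8-fold (3.43, SE 0.53), with 2 samples per age. miR-22-3p, abundant in striated muscle, rose 3.08-fold (1.62, SE 0.29), and let-7b rose 8.55-fold (3.10, SE 0.46). In epithelial miRNAs, miR-205a was 209-fold lower at P1 (-7.71, SE 1.23) and miR-205b was 73.2-fold lower (-6.19, SE 0.65). Some of these folds moved with single libraries. Without P1 replicate 2, miR-1a-3p had 4.68. Its mean was 1709 ± 1100 CPM at P1 (SD, n = 2), and its E11 libraries held only 16 and 20 counts. Without P1 replicate 1 and without P1 replicate 2, miR-205a had -10.54 and -6.80, and miR-205b -7.08 and -5.62. miR-499-3p had 3.19 without P1 replicate 1, miR-499-5p 4.05 without E11 replicate 1, and let-7b 3.70 without E11 replicate 1. Among these, miR-205a and miR-499-3p lost their call in 1 of the 6 such fits, miR-499-5p in 2 and let-7b in 1. miR-22-3p did not keep its call in every such fit either, and lost it in 3 of 21 alternatives.

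Of the 10 tested muscle miRNAs, 8 rose and none fell, and 9 rose when adjusted over the list alone. The others that rose were miR-133a-5p (3.23, SE 0.55), miR-133b (2.54, SE 0.72) and miR-1a-2-5p, which had 48 counts at P1 and 1 at E11, a ratio of 12.2 (95% interval 2.08 to 490). miR-133a-5p had 2.51 (adjusted p = 0.0263) without P1 replicate 2, miR-133b had 1.87 (adjusted p = 0.103) without E11 replicate 2 and 3.53 (adjusted p = 0.0502) without E11 replicate 1, and miR-1a-2-5p had 6.97 (adjusted p = 0.0621) without E11 replicate 2. miR-206 had 3336 ± 2173 CPM at P1 (SD, n = 2) and did not pass (1.06, edgeR Benjamini-Hochberg adjusted p = 0.153). The list's median was 3.47 and camera gave adjusted p = 9.58e-08, with adjusted p = 0.397 with an estimated correlation and 0.0152 in fry.

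In the epithelial list 5 of 7 tested members fell, and 6 when adjusted over the list alone. Besides the miR-205 pair these were miR-429-3p (-6.65, SE 1.64), miR-200b-3p (-5.87, SE 1.66) and miR-200a-5p, which had 71 counts at E11 and 1 at P1, a ratio of 280 (95% interval 48.7 to 11222). Without E11 replicate 2, miR-429-3p had -4.66 (adjusted p = 0.0971) and miR-200b-3p -3.76 (adjusted p = 0.175), and without P1 replicate 1 they had -9.65 (adjusted p = 0.0591) and -9.13 (adjusted p = 0.0736), and miR-200a-5p -8.99 (adjusted p = 0.0151). miR-203a, an epidermal miRNA, did not follow, with 660 and 362 CPM at E11 and 971 and 7.91 CPM at P1. The list's median was -6.19 and camera gave adjusted p = 8.72e-05, with adjusted p = 0.477 with an estimated correlation and 0.0513 in fry, and the median was -8.99 without P1 replicate 1 and -4.66 without E11 replicate 2. Its share of counts at P1 was 0.0997% in replicate 1 and 0.00309% in replicate 2.

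The miR-30 family rose, with 4 of 8 tested members up, 6 when adjusted over the list alone, and a median of 1.56 (camera adjusted p = 0.0144, adjusted p = 0.397 with an estimated correlation and 0.0152 in fry). miR-30a-5p rose 4.18-fold (2.06, SE 0.42) and miR-30e-5p 5.93-fold (2.57, SE 0.56), and their calls were lost in 5 and 6 of 21 alternatives. The calls of miR-30b-5p and miR-30d were lost in 8 and 10 of 21. In the miR-23, miR-24 and miR-27 clusters 3 of 4 members rose, 3 when adjusted over the list alone, with miR-27b-3p at 1.41 (SE 0.34), miR-24-3p at 1.45 (SE 0.44) and miR-23b-3p at 1.96 (SE 0.49), and the list was called by fry (adjusted p = 0.0152) but not by camera (adjusted p = 0.120). The calls of these 3 members were lost in 9, 12 and 8 of 21 alternatives. Both arms of miR-126, the endothelial miRNA, rose, miR-126-5p by 4.29-fold (2.10, SE 0.32) and miR-126-3p by 3.41-fold (1.77, SE 0.43). The call of miR-126-5p was lost in 0 and that of miR-126-3p in 8 of 21 alternatives.

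In the next 4 lists some members fell while camera did not call the list. Of 16 tested members of miR-17-92 and its paralogous clusters, 4 fell and 1 rose, 5 when adjusted over the list alone (camera adjusted p = 0.242, fry 0.0681). The 4 most abundant members did not pass, with miR-19b-3p at -0.40, miR-17-5p at -0.00119, miR-20a-5p at 0.33 and miR-20b-5p at -1.04. Apart from miR-92-3p, the members that passed had means of only 8.59 to 47.6 CPM over the 6 libraries. miR-92-3p was 2.84-fold lower (log2 SE 0.40), miR-92-5p 4.93-fold (SE 0.51), miR-18b-3p 9.89-fold (SE 0.71) and miR-19a-5p 7.34-fold (SE 0.55), while miR-17-3p rose (2.01, SE 0.59). In this order, their calls were lost in 8 of 21, 6 of 21, 7 of 21, 6 of 19 and 12 of 20 alternatives. Without E11 replicate 1, miR-18b-3p had -2.36 (adjusted p = 0.0652). miR-222a of the miR-221 and miR-222 cluster was 3.44-fold lower (-1.78, SE 0.38), the single call among 3 members, as it was when adjusted over the list alone, and fry called the list lower (adjusted p = 0.0372) where camera did not (adjusted p = 0.246). In the miR-181 family 2 of 3 members fell, also when adjusted over the list alone (camera adjusted p = 0.408, fry 0.190). miR-181a-3p fell by 1.59 (SE 0.39) and miR-181b-5p by 1.86 (SE 0.57) on the log2 scale, the latter with -0.68 without E11 replicate 1. Their calls were lost in 8 and 11 of 21 alternatives. The most abundant member, miR-181a-5p, had 0.21 (SE 0.43) and did not pass. In the miR-130 and miR-301 family 2 of 11 fell, also when adjusted over the list alone, the star arms miR-301a-5p (-2.04, SE 0.51) and miR-301b-5p (-1.88, SE 0.48), with camera adjusted p = 0.246 and fry 0.136. Fry called 4 of the 15 lists at P1 against E11, and its test for change in either direction 9.

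Some members of the blood lists rose, while neither camera nor fry called the lists with all 6 libraries. The medians were 1.94 (erythroid) and 1.52 (leukocyte), and 2.53 and 1.99 without P1 replicate 2. In the leukocyte list 4 of 8 members rose, 4 when adjusted over the list alone. They were miR-146a-5p (2.57, SE 0.52), miR-142-5p (2.40, SE 0.71), miR-146a-3p and miR-146b-5p. The list had camera adjusted p = 0.104 and fry 0.0860. Its most abundant member, miR-146c-5p, had -0.75 (SE 0.42), and the share of counts of the list went from 1.60% ± 0.832 at E11 to 0.756% ± 0.110 at P1 (SD, n = 2). Among 3 erythroid entries miR-451 rose 7.13-fold (2.83, SE 0.74), and all 3 passed when adjusted over the list alone (camera adjusted p = 0.153, fry 0.190). Without P1 replicate 1, miR-451 had 1.29 (adjusted p = 0.161) and miR-142-5p 1.28 (adjusted p = 0.178). In the let-7 list 1 of 14 members rose, let-7b, and 1 fell, let-7c-3p (-1.82, SE 0.57, and -2.45, adjusted p = 0.102, without P1 replicate 2), against 1 when adjusted over the list alone (camera adjusted p = 0.246). The median of the let-7 list was 0.52, and 1.01 without E11 replicate 1. In the miR-15 and miR-16 family miR-15a alone rose among 5 members (1.58, SE 0.48), against 0 when adjusted over the list alone (camera adjusted p = 0.515). The call of miR-15a was lost in 10 of 21 alternatives. No member of the HOX-embedded miR-10 and miR-196, miR-199 and miR-214 or neural lists passed, also when adjusted over the list alone, and neither camera nor fry called these lists.

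Lists too small for camera gave single results. miR-122-5p, the hepatocyte miRNA and sole tested liver marker, fell (-3.54, SE 1.02), but without E11 replicate 2 it had -0.51 (adjusted p = 0.763). miR-140-3p of the cartilage list had -2.50 (edgeR Benjamini-Hochberg adjusted p = 0.0692), with -0.58 without E11 replicate 1 and -3.31 without E11 replicate 2. No member of the miR-29, miR-26, miR-34 with miR-449 or miR-183 cluster lists passed over all entries in any comparison. Adjusted over the list alone, miR-29b-3p passed at P1 against E16 (adjusted p = 0.00786) and miR-26a-5p at P1 against E11 (1.39, adjusted p = 0.0498). For a single tested member that adjustment changes nothing, and at that level, with all 6 libraries, miR-140-3p passed at both ages against E11 and miR-122-5p at P1 against E16. In addition, no named entry of the smooth muscle list was present in the files used here. No named entry of the cluster of miR-302 and miR-367 had enough counts to be tested. The lists were matched by name, so unnamed entries could not be assigned to any of them.

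Outside the lists, the rule for the largest changes gave miR-31-5p, miR-1720-3p and miR-2954. miR-31-5p had 23.4 and 1841 CPM in the E11 libraries and 2.07 ± 1.33 CPM at P1 (SD, n = 2). Its log2 fold change was -8.71 (SE 2.20) and -3.41 (adjusted p = 0.164) without E11 replicate 2. miR-1720-3p fell (-4.11, SE 0.69), with -4.80 (adjusted p = 0.0801) without P1 replicate 1. miR-2954 rose by 3.88 (SE 1.18, edgeR Benjamini-Hochberg adjusted p = 0.0443), with 437 CPM in P1 replicate 1 and 8672 CPM in replicate 2, and had 0.55 (adjusted p = 0.470) without P1 replicate 2.

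**Figure D3:**
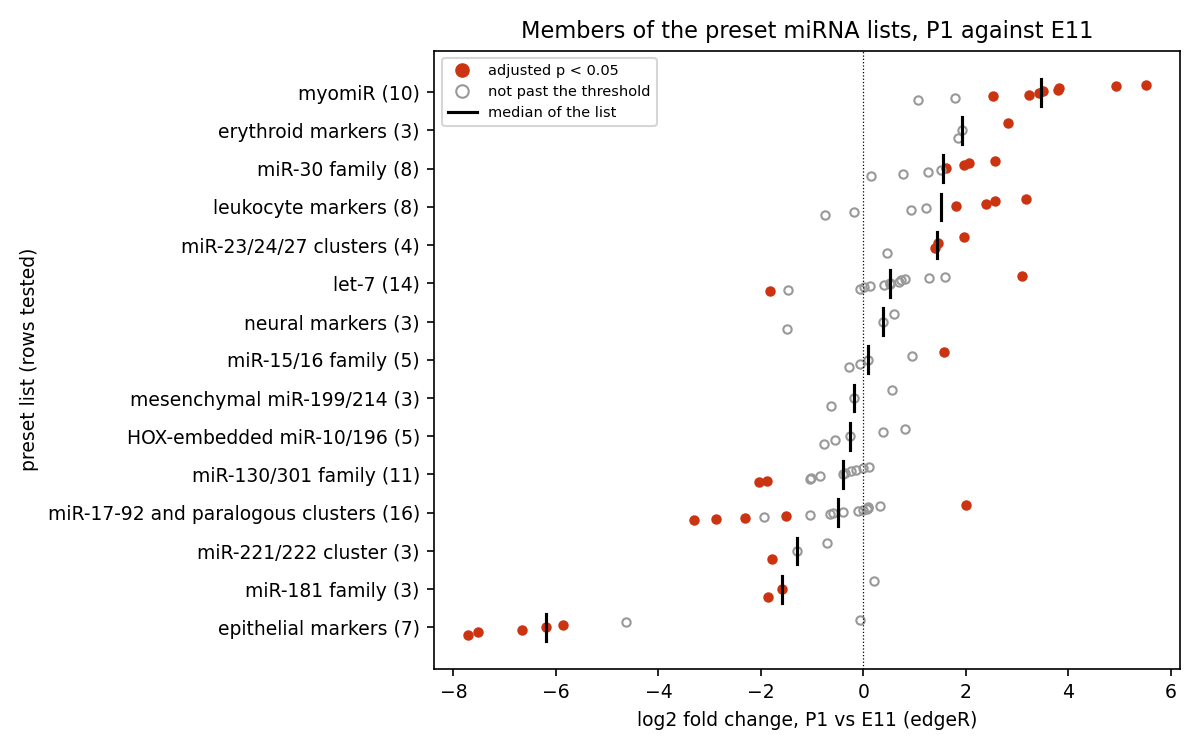
Log2 fold change from E11 to P1 of each tested member of the 15 tested lists, with filled points for members past an adjusted p of 0.05 in edgeR and a bar for the list median. The muscle list has a median of 3.47 and the epithelial list of -6.19.

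edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 88 of 289 entries at P1 against E11, 41 higher and 47 lower, of which 24 were unnamed (9 higher and 15 lower). Adjusted p was 0.00166 for miR-133a-3p, 0.00237 for miR-205b, 0.00444 for miR-1a-3p and miR-133c-3p, and 0.00646 for both miR-499 arms. Scaling by library size alone gave 20 higher and 64 lower. It moved the median log2 fold change of all entries by -0.47 here. The move was -0.16 at E16 against E11 and -0.30 at P1 against E16. In all 88 entries called in the main fit the samples of E11 and P1 did not overlap in CPM. A kept direction without 1 library was therefore close to fixed in advance and says little about stability. All 88 kept their direction when any 1 library was left out, where still tested, and 8 kept their call in every such fit, among them miR-1a-3p, miR-133a-3p, miR-133c-3p, miR-126-5p, miR-200a-5p and miR-205b. The count was 33 and 61 without E11 replicate 1 and 2, 21 and 10 without E16 replicate 1 and 2, and 19 and 23 without P1 replicate 1 and 2, and for 45 of the 88 the fold moved by over 1.5 times in at least 1 of these fits.

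The calls at E16 and at P1 against E11 overlapped. All 7 entries higher at E16 were also higher at P1, against 0.993 for independent lists, and all 12 lower at E16 were lower at P1, against 1.95. Simulated groups with no change gave a mean of 0 shared calls, but they gave a mean of only 0.13 calls over the 3 comparisons and so had almost none to share. The value for independent lists leaves out that both comparisons use the same 2 E11 libraries, so part of the excess may come from these shared libraries. With 1 E11 library for each comparison, chosen after seeing the data and with the lone library assumed to vary like the others, among 297 entries tested in both fits 3 of 4 higher and 4 of 6 lower calls at E16 were shared when E11 replicate 2 served E16 and replicate 1 served P1, against 0.35 and 0.71 for independent lists, and 2 of 2 and 3 of 4 the other way round, against 0.067 and 0.24.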

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

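The alternatives of named entries only, merged near-identical entries, thinning and removal of the epithelial list were chosen after seeing the data. No file lists a miRNA more than once, so keeping the larger of repeated entries gave no value. Where an age was left with 1 library, that library was assumed to vary like the others. The next counts cover the miRNAs picked for mention in the text, many of them for large or called changes, and not all named entries. At E16 against E11, 333 alternative results kept their direction and side of the threshold, 72 lost the call and 21 gained one. At P1 against E16 the numbers were 323, 0 and 8, and at P1 against E11 763, 307 and 8, with 10 reversed. The depth of the E11 libraries limits low-count miRNAs.

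The 19 calls at E16 against E11 became 38 with DESeq2, 46 with no filter, 12 with named entries only and 0 to 11 when 1 library was left out. The 0 calls at P1 against E16 became 2 with DESeq2, 13 with no filter and 0 to 1 when 1 library was left out, the 1 being miR-2954 without P1 replicate 1. The 88 calls at P1 against E11 became 28 with only the 4 samples compared, where fewer samples estimate the spread, and 10 to 61 when 1 library was left out. With the replicate block they became 30, and the block gave 13 calls at E16 against E11 and 0 at P1 against E16. Deviations of same-numbered samples correlated by -0.02 between E11 and E16, -0.03 between E11 and P1 and 0.33 between E16 and P1. The main fits did not pair the samples by number. For E16 and P1 the 0.33 leaves open a factor shared by same-numbered samples. In that comparison the replicate block called 5 lists, the same number as the main fit.

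The 2 lists at E16 against E11 became 4 with no filter, 1 without the epithelial list (by construction) and 0 with an estimated correlation, with 2 to 3 when 1 library was left out. The 5 lists at P1 against E16 became 3 with library size only, 3 with entries listed in all 6 files, 3 with named entries only, 2 with at least 10 counts in every sample of 1 age, 2 after thinning, 0 with an estimated correlation and 1 to 5 when 1 library was left out. The 3 lists at P1 against E11 became 8 with no filter, 0 with an estimated correlation and 3 to 5 when 1 library was left out.

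The muscle share of 1.16% at E11 was 0.980% without miR-206 and 1.98% with named entries only (1.04% to 1.28% by library). At E16, 7.64% became 8.44% without the most abundant entry outside the list, 7.19% without miR-206 and 12.2% with named entries only (7.37% to 7.92%). At P1, 13.7% became 20.6% with named entries only (12.1% to 15.4%). These changes follow from the altered numerator or denominator.

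Reversals occurred in 3 uncalled miRNAs at P1 against E11. miR-203a, at -0.06 (log2), was 0.0923 with RLE, 0.0905 with DESeq2, 0.36 with no filter, 0.12 with entries listed in all 6 files and 0.0277 with merged entries, and between -6.06 and 0.96 when 1 library was left out, with 0.52 without E11 replicate 1 and 0.07 without E16 replicate 2. let-7f-5p, at 0.52, was -0.00568 without E11 replicate 2, and up to 1.32 without E11 replicate 1. miR-223, at 0.94, was -0.15 without P1 replicate 1, within -0.15 to 1.60. The cause was not tested for the counts, lists and reversals, except where stated.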

Other observations

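Some miRNAs outside the lists also changed from E11 to P1. Both arms of miR-193a rose, miR-193a-3p by 3.53-fold (log2 fold change 1.82, SE 0.50) and miR-193a-5p by 4.14-fold (2.05, SE 0.51), and both arms of miR-455, a miRNA of cartilage and other mesenchyme, fell, miR-455-5p by 1.61 (SE 0.38) and miR-455-3p by 2.25 (SE 0.61) on the log2 scale, with 2 samples per age. miR-2188-5p rose 6.03-fold (2.59, SE 0.70), with 3369 CPM in P1 replicate 1 and 807 CPM in replicate 2, and had 1.16 (adjusted p = 0.171) without replicate 1, and miR-455-3p had -1.58 (adjusted p = 0.0947) without E11 replicate 1. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment these passed with adjusted p between 0.0255 and 0.0353, but each lost its call in 1 or more fits without a single library.

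The tests in this part were chosen after the results were seen, except the search for other raised miRNAs in P1 replicate 2 and the comparison of arms, and 2 of them were altered after a first run: the threshold of the chromosome Z test was set to 2 standard errors, and a test of random sets replaced a test of depth for the blood markers. Across 47 hairpins with both arms tested, 35 had arms with the same sign at P1 against E11, against a mean of 23.5 in random pairings, and the mean product of the fold changes exceeded that of random pairings (permutation p = 1e-04, the smallest that 10000 pairings can give). Where both arms passed, in 8 hairpins, their signs were the same. Where 1 arm passed, in 15 hairpins, 13 had arms of the same sign. The signs differed in miR-17 (5p -0.00119, 3p 2.01) and miR-181a (5p 0.21, 3p -1.59). The other arm could also be nearly flat, as in miR-19a (5p -2.87, 3p -0.11). The mean product gives most weight to large changes such as miR-200a (5p -7.53, 3p -4.62). These values go with the hypothesis that the 2 arms of a hairpin change together with age, as a tendency and not in every hairpin.

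miR-2954 had 8672 CPM in P1 replicate 2 and between 307 and 437 CPM in the other 5 libraries. In birds miR-2954 is encoded on chromosome Z and is higher in males, while the labels give all samples as female. Depth or scaling does not account for it, since either would move all entries of a library alike. The ratio of the P1 libraries was at least 16.9 under 4 scalings and thinning. The upper end of the central range of other entries was 2.85 or less. Trying other scalings could hardly end otherwise, since miR-2954 was picked as the outlier. Tissue of another kind is argued against as well, since 0 other entries at 100 CPM or more were 8-fold higher there (the highest, miR-3607-3p, was 3.86-fold higher). Male or mixed-sex tissue stays open: 5 entries with a chromosome Z identifier had a median log2 ratio of 0.77 (SE 0.59, from -0.48 to 1.96), too few and too scattered to decide.

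The 6 tested epithelial miRNAs other than miR-203a were higher in both E11 libraries than in any later library. A dilution of all other cell types alike by muscle RNA is argued against, since the endothelial miR-126-5p rose from E11 to P1 (2.10), between 1.97 and 2.24 when any 1 library was left out, and the endothelial, erythroid and leukocyte medians were above 0, the smallest at 1.52 (log2). The blood lists add little, since camera called neither, the leukocyte share of counts went from 1.60% to 0.756%, and without P1 replicate 1 miR-451 had 1.29 and miR-223 -0.15. Cartilage miR-140-3p (-2.50, adjusted p = 0.0692) and liver miR-122-5p (-3.54) were lower at P1, but had -0.58 without E11 replicate 1 and -0.51 without E11 replicate 2, so whether some cell types were diluted stays open. The count ratio of miR-203a to miR-205a was 0.103 and 0.102 at E11, 2.46 and 0.75 at E16, and 22.3 and 2.33 at P1. The range was 219-fold. For this pair, 1 epithelium of fixed composition as the only source is argued against. The pair was chosen after miR-203a was seen not to follow, so the ratio restates that difference and does not reach the other members. For the other 6, a larger amount of epithelium in the E11 tissue stays open. So do skin of changing composition in the dissected tissue, which may differ with age, and a change with age within the muscle. Neither of the latter was tested.

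Blood markers were higher in P1 replicate 1 than in replicate 2. The median ratio over the 3 erythroid entries was 3.42, and the miR-142 and miR-223 entries were 2.73 to 3.20 times higher. These entries are the ones that drew attention, so the ratios restate the pattern and leave open both a larger blood content of the P1 replicate 1 tissue and ordinary scatter between the 2 P1 libraries, as large in any set of entries. The 11 entries of the erythroid and leukocyte lists had a median log2 ratio of 1.42 against -0.21 for all entries. None of 10000 random sets reached that median, a share of 1e-04 with the observed set included. This decides nothing, since the lists were picked for the difference and arms or clusters made from 1 transcript are not independent. The 2 P1 libraries differed in other lists as well. Replicate 1 and replicate 2 had epithelial shares of counts of 0.0997% and 0.00309%. The muscle share went the other way, with 12.1% and 15.4%, as did the endothelial share, with 5.04% and 5.96%. Whether these differences share a cause with the blood markers was not tested. The labels give no difference between the 2 samples, so no biological explanation was tested beyond the blood content of the tissue.

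The count ratio of miR-133a-3p to miR-1a-3p lay between 56.0 and 123 in the 6 libraries. The reason for the lower counts of miR-1a-3p was not tested.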
